A study of Homo sapiens with 19 samples.

How the data were processed

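Messenger RNA was measured on 19 Illumina HumanHT-12 V4 expression beadchip arrays, 1 array per sample, in 7 groups of cultured human breast cancer cells. Per the labels the groups were the parental MDA-MB-231 line (MD231, 3 arrays), a parental culture given as the parent of the brain line (MD231p, 3 arrays), a tumour-derived line (TMD231, 2 arrays) and lines from metastases to the adrenal gland (ADMD231, 3 arrays), bone (BMD231, 3 arrays), lung (LMD231, 2 arrays) and brain (BrMD231, 3 arrays). The series text names biological triplicates, but TMD231 has replicates 1 and 2 alone and LMD231 replicates 1 and 3 alone. The p-values below therefore measure the spread between the samples of a line. The chip numbers in the deposited column names place 11 arrays on 1 beadchip (beadchip 1) and 8 on another (beadchip 2), with every group on both.

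The deposited table gives, per the file headers, an average signal intensity and a detection p-value for each of 47323 probes on each array. The authors' signal values are on a linear scale and are not normalized between arrays. The deposited detection p-values compare a probe with the negative-control beads of its own array, in steps that fit 770 controls. GenomeStudio and Partek are the programs named, per the submitters' processing notes, with no version. The authors' second table, the series matrix, holds intensity values for 47317 probes on a linear scale, with array medians of 11.738 throughout and about 26.7% of values below 0. How those values were made and centred is not stated, and no genome build or aligner is given in the sources used here. The ranks within each array of that table equalled those of the same array's signal (Spearman coefficient 1).

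Signals were background-corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16 and the negative-control level inferred from the detection p-values, and were taken to log2. Probes were kept when their detection p was under 0.05 on at least 50% of the arrays of at least 1 group, which left 22784 probes. Symbols were brought to current names through the transcript accession (27607 probes), then through the deposited symbol or a synonym (4779 probes), and 11667 probes kept the deposited name. The 1624 kept probes without a symbol were left out of the gene tests; tested by themselves, 0 passed the limma threshold in any comparison. For a gene with several kept probes (3829 genes) the probe with the highest mean stood for the gene, leaving 16318 genes, of which 3344 carry provisional LOC symbols.

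Groups were compared with limma, in a single model of all 19 arrays with group as the only term (12 residual degrees of freedom), by two-sided moderated tests with Benjamini-Hochberg adjustment over the genes of each comparison and an adjusted p threshold of 0.05. The comparisons were each of ADMD231, BMD231, LMD231 and TMD231 against MD231, BrMD231 against MD231p, MD231p against MD231, each of 3 metastatic lines against TMD231, each of these 3 against the mean of the other two, and the change of BrMD231 from MD231p against the mean change of the 3 lines from MD231. The model, filter, gene lists, comparisons and alternative settings were fixed before the data were examined. Errors of log2 fold changes are standard errors (SE) from the model and errors of levels are standard deviations (SD). The same model with the beadchip as a block (11 residual degrees of freedom), with the replicate number as a block (10), and within beadchip 1 (4) and beadchip 2 (1) gave the values that stand beside the results. Within beadchip 2 the spread comes from a single pair of arrays, ADMD231 replicates 2 and 3, so its counts rest on that pair.

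Genes were named by a rule fixed with the comparisons. For each main comparison it takes the 8 largest rises and 8 largest falls among genes past the threshold whose arrays do not overlap between the groups and that are detected on at least 1 array of each. It adds up to 3 genes in each direction that were detected on every array of one group and on none of the other, and up to 4 members past the threshold of each gene list called. Other comparisons take 5 genes each way, and those of 2 groups also the genes detected in only 1 of them, and the shared change takes 8 each way. LOC symbols are passed over, and genes named outside the rule are marked as chosen after their values were seen. Where a gene was undetected on every array of a group, its fold is given as a lower bound, computed against the lowest detected intensity of each of those arrays. Other kept probes of a named gene are given where their log2 change was below the bound or under 0.5 of that of its probe. The number of arrays limits the precision of every value.

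Gene lists for pathways, metastasis genes and cell types (46 lists, 45 with at least 5 genes tested) were compared with all other genes by camera of limma, with the preset correlation of 0.01 between genes of a list and adjustment over the 45 lists of each comparison. The metastasis lists of this cell line were fixed from earlier literature, not these arrays. Each holds MMP1, as do matrix proteases, so their calls are not independent. Camera was also run with a correlation estimated per list, and the rotation test fry was run beside it. Fry tests a list against no change, where camera tests it against the other genes. Members were also counted past a threshold adjusted over the list alone.

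Whether replicate numbers pair the samples was checked from the correlation across genes of the replicate-to-replicate deviations, where genes are not independent replicates. The coefficients were 0.57 to 0.90 for BMD231 and MD231, 0.70 to 0.95 for BrMD231 and MD231p and 0.48 to 0.88 for MD231p and MD231, above the bound of 0.1 for taking numbers as pairs. They ranged over -0.43 to 0.84 for ADMD231 and MD231 and -0.56 to 0.72 for TMD231 and MD231, which did not meet it. Over all comparisons of 2 groups the 18 same-numbered pairs that share a beadchip had coefficients above 0 and the 3 others below 0, so these coefficients follow the beadchip. Within beadchip 1 the differences between replicates 1 and 2 had coefficients of 0.24, 0.53 and 0.02 in the same order, a check added after seeing the data. For MD231p and MD231 pairing apart from the beadchip is therefore not shown. The replicate-block values are printed beside the results. On simulated data with a beadchip difference like the measured one, the model without a block recovered 0 of 67 changes of log2 1, 10 of 67 of log2 2 and 45 of 66 of log2 4 for BMD231 against MD231, with 0 false calls. With the block it recovered 16, 42 and 65, with 7 false calls. The list test called the 1 raised list and 0 of the others in the simulation.

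Alternatives changed one choice at a time: the background correction, scaling between arrays, filter, probe per gene, variance model, arrays in the model, blocks, each beadchip alone, the authors' processed values, and each array left out. A model with the beadchip as a block and weights that let the beadchips differ in spread, and the list test within each beadchip, were added after seeing the data. Gene lists from the authors' own ANOVA were not used here.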

Results

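The arrays measured messenger RNA levels in MDA-MB-231, a human breast cancer line, and in lines derived from it by growth as a tumour or as metastases in 4 organs, to find how the lines of each organ differ. MD231 stood on 3 arrays, MD231p on 3, TMD231 on 2, ADMD231 on 3, BMD231 on 3, LMD231 on 2 and BrMD231 on 3. The number of probes detected per array ran from 8752 for MD231 replicate 2 to 18360 for BrMD231 replicate 3, and the median signal from 70.4 for ADMD231 replicate 1 to 95 for TMD231 replicate 2. The 11 arrays of beadchip 1 detected 8752 to 12161 probes, and the 8 arrays of beadchip 2 detected 17199 to 18360. The 95th percentile of signal was 247 to 976 on beadchip 1 and 1265 to 1572 on beadchip 2.

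The beadchip was the main axis of variation, and the first principal component, with 71.1% of the variance, parted the 2 beadchips. MD231 replicate 2 lay apart from the other arrays on the second component (8.62%). With group and beadchip in the limma model, 12256 of 16318 genes differed between beadchips, 5427 higher and 6829 lower on beadchip 2. The median absolute difference was 0.996 log2 units. The ribosomal protein gene RPLP0 averaged 6.03 ± 0.696 (SD, n = 11) on beadchip 1 and 13.9 ± 0.175 (SD, n = 8) on beadchip 2. GAPDH, a glycolytic enzyme, averaged 9.11 ± 0.427 (SD, n = 11) and 12.8 ± 0.16 (SD, n = 8). Both genes were higher on beadchip 2 under median scaling and cyclic loess too, at 5.4 against 14.0 for RPLP0 under the first of these. ADMD231, LMD231 and TMD231 are split unlike MD231, so their folds without a block carry some beadchip difference.

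**Figure D1:**
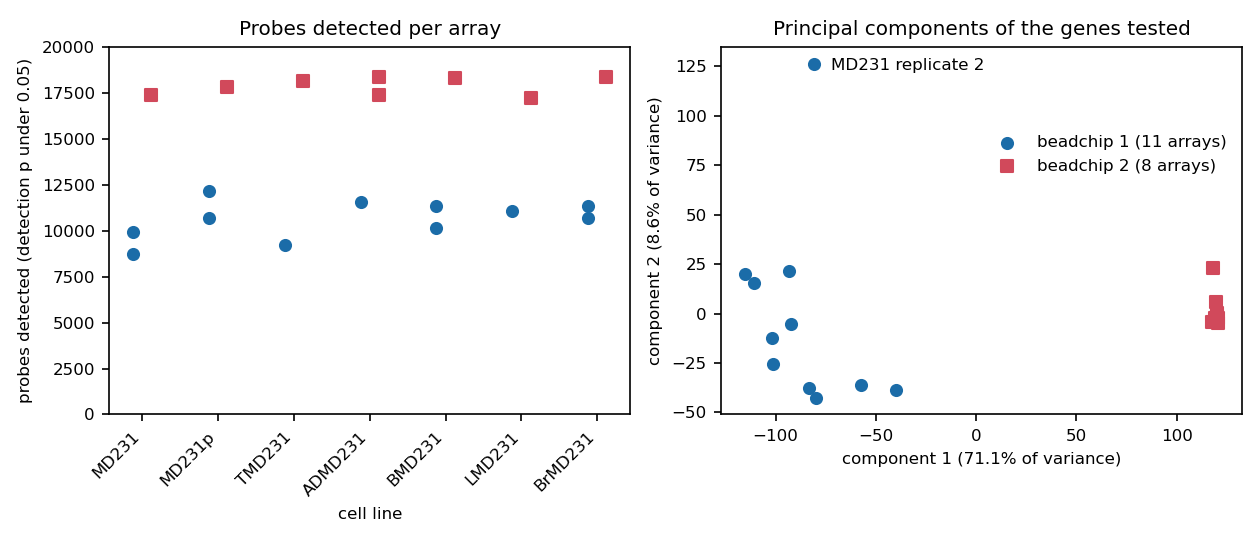
Each point is 1 of the 19 arrays; the panels plot the number of probes detected and the scores on the first principal components, by group and beadchip. The 8 arrays of beadchip 2 detected 17199 to 18360 probes and the 11 of beadchip 1 detected 8752 to 12161.

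The first question was how the adrenal line differed from the parental line. In ADMD231 against MD231 (3 arrays each), MMP1, an interstitial collagenase on chromosome 11, rose 335-fold (log2 8.39 ± 0.65, adjusted p = 7.61e-06), from 5.7 ± 1.17 to 14.1 ± 0.163 log2 intensity (SD, n = 3 each). MMP1 was detected on 1 of the 3 MD231 arrays. AOX1, an aldehyde oxidase, rose 22.5-fold (log2 4.49 ± 0.62, adjusted p = 0.00232) and LRRC20 rose 12.9-fold (log2 3.68 ± 0.35, adjusted p = 6.80e-05). CCND2, a D-type cyclin, rose 48.6-fold (log2 5.60 ± 1.13, adjusted p = 0.0494). ARMCX2 rose 12.6-fold and PLPP3, a lipid phosphatase listed as PPAP2B, rose 11.5-fold; ST3GAL6, a sialyltransferase, rose 12.2-fold and MAP3K7CL, listed as C21ORF7, rose 17.1-fold. A further 3 genes were undetected on every MD231 array, so that their folds are lower bounds. ESM1, a secreted proteoglycan, was at least 32.2-fold (log2 6.20 ± 0.90, adjusted p = 0.00389) higher, CDH11, a mesenchymal cadherin, at least 19.3-fold (log2 5.83 ± 0.41, adjusted p = 4.86e-06) higher, and PGM5, a cell-adhesion protein, at least 19.2-fold (log2 5.40 ± 0.64, adjusted p = 0.000639) higher.

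Among the genes that fell in ADMD231 were the structural protein genes COL18A1 (collagen XVIII), TGFBI (a matrix protein) and GJB2 (connexin 26). COL18A1 fell 7.57-fold (log2 -2.92 ± 0.57), TGFBI 5.73-fold (log2 -2.52 ± 0.40) and GJB2 6.41-fold (log2 -2.68 ± 0.36). VIPR1, a receptor for vasoactive intestinal peptide, fell 26.2-fold (log2 -4.71 ± 0.93, adjusted p = 0.0453), the homeobox gene IRX3 fell 4.71-fold (log2 -2.24 ± 0.28, adjusted p = 0.000969), ARHGAP15 fell 6.37-fold and ZNF415 fell 6.6-fold. FLG, which encodes the epidermal protein filaggrin, was undetected in ADMD231 and at least 36.1-fold (log2 -6.17 ± 0.47, adjusted p = 7.61e-06) lower. SCG2, a secretory granule protein, was at least 26.1-fold (log2 -4.82 ± 0.36, adjusted p = 7.61e-06) lower, the drug efflux transporter ABCC3 at least 16.7-fold lower (adjusted p = 0.0242), and THBS2, an anti-angiogenic thrombospondin, at least 13.7-fold (log2 -4.67 ± 0.23, adjusted p = 7.64e-08) lower. On at least 1 array of the lower group MMP1, CCND2, AOX1, MAP3K7CL, ARMCX2, ST3GAL6, PLPP3, ZNF415 and ARHGAP15 were undetected, so their folds rest in part on background. Other probes of CCND2 (2.64), PLPP3 (1.36), ESM1 (3.47) and PGM5 (2.75 and 1.59) gave smaller log2 changes in the same direction. In all, 61 of 16318 genes passed the threshold, 45 higher and 16 lower. The arrays of the groups did not overlap for 1655 genes (10.1%, where chance gives 10%). With the beadchip as a block 627 genes passed (426 higher, 201 lower), and with the replicate number as a block 165. Beadchip 1 alone gave 49 genes and beadchip 2 alone 5401. With only the 2 groups in the model, 8 genes passed (688 at an unadjusted p under 0.05). All 61 genes were called with either block and moved the same way within both beadchips, for MMP1 by 8.31 and 8.80 log2. The calls were 210 higher and 29 lower under median scaling, and numbered 36, 31 and 32 without ADMD231 replicates 1, 2 and 3. They were 28 higher and 18 lower without MD231 replicate 2 and 44 higher and 72 lower without MD231 replicate 3. Of 23 named genes 14 stayed past the threshold whichever array was left out, while ABCC3, CCND2, COL18A1, MAP3K7CL, PLOD2, ST3GAL6, TGFBI, VIPR1 and ZNF415 did not for at least 1 array.

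Of 45 gene lists, 10 passed in ADMD231 against MD231, 7 up and 3 down. Brain metastasis genes of this cell line rose as a list (median log2 1.10; adjusted p = 1.76e-07, and adjusted p = 0.00286 with an estimated correlation). The median was 0.97 with undetected members at their bound, 0.96 with the beadchip as a block, and 0.76 and 1.19 within beadchips 1 and 2. Of 14 members 2 passed over all genes and 6 adjusted over the list alone, among them MMP1 and the collagen-modifying enzyme PLOD2 (log2 1.31 ± 0.25, adjusted p = 0.0414). PTGS2, a prostaglandin synthase undetected in MD231, was at least 7.03-fold (log2 3.82 ± 1.08) higher and FSCN1, an actin-bundling protein, had log2 1.93 ± 0.53, both short of the threshold over all genes. The bone metastasis list passed upward (median log2 1.83; adjusted p = 4.48e-07, and adjusted p = 0.0668 with an estimated correlation). Within beadchips 1 and 2 the median was 0.99 and 1.38, with the beadchip as a block 1.30, and with undetected members at their bound 1.49. Over all genes 1 of 10 members passed, namely MMP1, and 5 adjusted over the list alone. The lung metastasis list passed upward (median log2 0.71; adjusted p = 0.00494, and adjusted p = 0.286 with an estimated correlation). That median was 0.74 with the beadchip as a block, 0.87 and 0.20 within beadchips 1 and 2, and 0.45 with undetected members at their bound. Adjusted over the list alone 3 of 19 members passed, and over all genes 1. The NRF2 target list passed downward (median log2 -0.41, but 0.44 under median scaling, where all genes had a median of 0.47; adjusted p = 0.0274, and adjusted p = 0.0691 with an estimated correlation). Undetected members at their bound gave a median of -0.41, the beadchip as a block -0.45, and beadchips 1 and 2 alone -0.34 and -0.25. Members past the threshold were 3 of 22 adjusted over the list alone and 1 over all genes, and ABCC3 was the member that fell. The collagen and matrix list passed downward (median log2 -0.45; adjusted p = 0.00891, and adjusted p = 0.0519 with an estimated correlation). The median was -0.45 with undetected members at their bound, -0.39 with the beadchip as a block, and -0.14 and -0.20 within beadchips 1 and 2. Of 25 members 1 passed over all genes and 3 adjusted over the list alone. Matrix proteases passed upward at adjusted p = 0.00891, and 0.0519 with an estimated correlation. NF-kB targets (median 0.25, and -0.16 within beadchip 2), ERK output and immediate early genes passed upward at 0.0493, 0.0397 and 0.0493, and leukocyte markers (median -0.76, -0.66 at the bounds) downward at 0.0397. With an estimated correlation these were 0.286, 0.324, 0.324 and 0.511, and by fry 0.0572, 0.241, 0.231 and 0.395. Blocking on the beadchip kept 6 of the 10 calls, and these 4 missed the threshold at 0.143, 0.106, 0.0975 and 0.433.

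The bone line was compared with the parental line in the same way. In BMD231 against MD231 (3 arrays each), MMP1 rose 322-fold (log2 8.33 ± 0.65, adjusted p = 6.96e-06) and AOX1 rose 16-fold (log2 4.00 ± 0.62, adjusted p = 0.00688). UBASH3B, a phosphatase listed as STS-1, rose 42.5-fold (log2 5.41 ± 0.96, adjusted p = 0.0192). BST2, an interferon-induced antiviral membrane protein, rose 26-fold (log2 4.70 ± 0.81, adjusted p = 0.0168), and ADGRF5, an adhesion G protein-coupled receptor listed as GPR116, rose 14.8-fold (log2 3.89 ± 0.38, adjusted p = 7.71e-05). SEL1L3 rose 14.9-fold, ST3GAL6 14.8-fold and LRRC20 13.4-fold. Against MD231, where they were undetected, ESM1 was at least 43-fold (log2 6.62 ± 0.90, adjusted p = 0.00219) higher, AGR2, a protein disulfide isomerase of secretory cells, at least 22.9-fold (log2 5.91 ± 0.50, adjusted p = 1.60e-05) higher and CDH11 at least 20.4-fold (log2 5.91 ± 0.41, adjusted p = 4.04e-06) higher. SCG2 fell 27-fold (log2 -4.75 ± 0.36, adjusted p = 6.96e-06), COL18A1 fell 8.21-fold, LXN, a carboxypeptidase inhibitor, fell 6.13-fold, IRX3 fell 5.56-fold and GJB2 fell 4.56-fold. FLG was at least 27.6-fold lower, THBS2 at least 10.5-fold lower and the autophagy gene MAP1LC3A at least 8.4-fold lower, all undetected in BMD231.

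The folds of MMP1, UBASH3B, BST2, AOX1, SEL1L3, ADGRF5, ST3GAL6, SCG2, COL18A1, LXN, RGCC and ROBO1 rest in part on background, as at least 1 array of the lower group did not detect them. Smaller log2 changes in the same direction came from other probes of LRRC20 (1.06), ESM1 (1.41), AGR2 (1.60), MAP1LC3A (-0.38) and PLOD2 (0.47). For the bone line, 53 of 16318 genes passed the threshold, 39 higher and 14 lower. Arrays of the groups did not overlap for 950 genes (5.82%). The count was 106 on beadchip 1 alone and 4249 on beadchip 2 alone. Blocking on the beadchip, 682 genes passed (442 higher, 240 lower), and blocking on the replicate number 151. A limma model of only the 2 groups called 5 genes (404 at an unadjusted p under 0.05). All 53 genes were called with either block and moved the same way within both beadchips, for ESM1 by 7.24 and 5.36 log2. Calls were 139 higher and 22 lower under median scaling, 31 and 34 genes without BMD231 replicates 1 and 2, 23 higher and 18 lower without MD231 replicate 2 and 33 higher and 51 lower without MD231 replicate 3. With any 1 array left out 12 of the 22 named genes stayed past the threshold, and BST2, COL18A1, GJB2, LXN, PLOD2, RGCC, ROBO1, SEL1L3, ST3GAL6 and UBASH3B did not for at least 1 array. Of the gene lists 6 passed, 5 up and 1 down. The brain metastasis list rose (median log2 0.77; adjusted p = 9.51e-10, and adjusted p = 0.000845 with an estimated correlation). Within beadchips 1 and 2 the median was 0.76 and 1.02, with the beadchip as a block 0.77, and with undetected members at their bound 0.18. Over all genes 3 of 14 members passed, and 5 adjusted over the list alone. Its members past the threshold were MMP1, RGCC, a cell-cycle regulator (log2 3.39 ± 0.55), and PLOD2 (log2 1.38 ± 0.25). The bone metastasis list, fixed from lines of this organ, passed upward (median log2 0.96; adjusted p = 0.000122, and adjusted p = 0.136 with an estimated correlation). That median was 0.96 with the beadchip as a block, 0.27 and 1.23 within beadchips 1 and 2, and 0.00 with undetected members at their bound. Adjusted over the list alone 2 of 10 members passed, and over all genes 1. FST, the activin antagonist of that list, had log2 4.34 ± 1.29 and was detected on 1 of 3 MD231 arrays. The endothelial list passed upward (adjusted p = 0.00421, adjusted p = 0.115 with an estimated correlation), and its member ROBO1, a guidance receptor, rose (log2 2.38 ± 0.42, adjusted p = 0.0179). The lung metastasis list and NF-kB targets passed upward and NRF2 targets downward (median -0.46), at adjusted p = 9.89e-06, 0.00421 and 0.00641. With an estimated correlation these became 0.0929, 0.0929 and 0.0724.

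The lung line stood on 2 arrays against 3 of the parental line. In LMD231, MMP1 rose 344-fold (log2 8.43 ± 0.73, adjusted p = 2.48e-05) and AOX1 rose 21.1-fold (log2 4.40 ± 0.69, adjusted p = 0.0104). RGCC rose 14.1-fold (log2 3.82 ± 0.61, adjusted p = 0.0125), LRRC20 13.1-fold (log2 3.71 ± 0.39, adjusted p = 0.000257) and ADGRF5 11.4-fold (log2 3.51 ± 0.43, adjusted p = 0.00102). MYO5C, an unconventional myosin, rose 11.3-fold, ARMCX2 10.9-fold and PLPP3 9.52-fold. The genes undetected in MD231 included ESM1, at least 38.6-fold (log2 6.46 ± 1.00, adjusted p = 0.0104) higher, CDH11, at least 26.2-fold (log2 6.27 ± 0.46, adjusted p = 6.77e-06) higher, and AGR2, at least 18.5-fold (log2 5.60 ± 0.56, adjusted p = 0.000136) higher. IRX3 fell 6.26-fold (log2 -2.65 ± 0.31, adjusted p = 0.000714), GJB2 5.23-fold (log2 -2.39 ± 0.40, adjusted p = 0.019) and ARHGAP15 5.08-fold. FLG was at least 31.4-fold lower, SCG2 at least 22.7-fold lower and THBS2 at least 11.9-fold (log2 -4.67 ± 0.26, adjusted p = 3.64e-07) lower.

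On at least 1 array of the lower group MMP1, AOX1, RGCC, ADGRF5, MYO5C, ARMCX2, PLPP3 and ARHGAP15 were undetected, so their folds rest in part on background. Other probes of LRRC20 (1.68), PLPP3 (0.89), ESM1 (2.74) and AGR2 (1.60) gave smaller log2 changes in the same direction. In the lung line 41 of 16318 genes passed the threshold, 30 higher and 11 lower. The arrays of the groups did not overlap for 1667 genes (10.2%). When the beadchip was a block 441 genes passed (317 higher, 124 lower), and when the replicate number was a block 90 did. Within beadchip 1 alone 46 genes passed and within beadchip 2 alone 4467. With only the 2 groups in the model, 0 genes passed (260 at an unadjusted p under 0.05). All 41 genes were called with either block and moved the same way within both beadchips, for CDH11 by 6.57 and 5.99 log2. Median scaling gave 108 higher and 20 lower, and the counts were 18 and 12 without LMD231 replicates 1 and 3, which leaves a lone array assumed to vary like the other groups. They were 18 higher and 10 lower without MD231 replicate 2 and 30 higher and 34 lower without MD231 replicate 3. Of 17 named genes 9 stayed past the threshold with any 1 array left out, and AOX1, ARHGAP15, ARMCX2, ESM1, GJB2, MYO5C, PLPP3 and RGCC did not for at least 1 array. Of the lists 6 passed, 4 up and 2 down. The brain metastasis list rose (median log2 0.81; adjusted p = 1.39e-08, and adjusted p = 0.00154 with an estimated correlation). Undetected members at their bound gave a median of 0.68, the beadchip as a block 0.67, and beadchips 1 and 2 alone 0.40 and 1.02. Members past the threshold were 5 of 14 adjusted over the list alone and 2 over all genes. The lung metastasis list, fixed from lines of this organ, passed upward (median log2 0.44; adjusted p = 0.00136, and adjusted p = 0.198 with an estimated correlation). The median was 0.45 with undetected members at their bound, 0.36 with the beadchip as a block, and 0.09 and 0.12 within beadchips 1 and 2. Of 19 members 1 passed over all genes and 5 adjusted over the list alone. In that list IL13RA2, a decoy receptor for interleukin 13 undetected in MD231, was at least 3.23-fold (log2 3.07 ± 1.01) higher, short of the threshold over all genes. By fry the lung metastasis list missed the threshold (adjusted p = 0.0635), as did NF-kB targets (0.0797, and 0.0962 by camera with the beadchip as a block). Bone metastasis genes and NF-kB targets passed upward at adjusted p = 3.35e-06 and 0.0328, and 0.0992 and 0.198 with an estimated correlation. NRF2 targets (median -0.28) and matrix proteins (median -0.20, but 0.01 under median scaling) passed downward at 0.0055 and 0.00986, and 0.0522 and 0.0522 with an estimated correlation.

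The tumour-derived line was compared with the parental line next. In TMD231 (2 arrays against 3), MMP1 rose 53.7-fold (log2 5.75 ± 0.73, adjusted p = 0.00221), BST2 43.4-fold (log2 5.44 ± 0.91, adjusted p = 0.0264) and ADGRF5 31.3-fold (log2 4.97 ± 0.43, adjusted p = 2.96e-05). ARMCX2 rose 11.9-fold, SERPINB2, a plasminogen activator inhibitor, 7.08-fold (log2 2.82 ± 0.51, adjusted p = 0.0423) and the receptor tyrosine kinase gene MERTK 6.06-fold (log2 2.60 ± 0.46, adjusted p = 0.0423). Against MD231, where they were undetected, CDH11 was at least 13.6-fold (log2 5.33 ± 0.46, adjusted p = 2.96e-05) higher, LRATD2, listed as FAM84B, at least 8.6-fold (log2 4.69 ± 0.32, adjusted p = 4.16e-06) higher, and KYNU, a tryptophan-degrading enzyme, at least 6.11-fold (log2 4.27 ± 0.77, adjusted p = 0.0423) higher. SCG2 fell 19-fold (log2 -4.25 ± 0.40, adjusted p = 8.79e-05), ARHGAP15 6.59-fold and IRX3 4.64-fold. FLG was at least 26.9-fold lower, THBS2 at least 10.2-fold lower, and PDE9A, a cyclic GMP phosphodiesterase, at least 3.64-fold lower.

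The folds of MMP1, BST2, ADGRF5, ARMCX2, SERPINB2, MERTK, SCG2 and ARHGAP15 rest in part on background, as at least 1 array of the lower group did not detect them. Smaller log2 changes in the same direction came from other probes of SERPINB2 (1.39), MERTK (0.48), KYNU (0.72) and LAMA4 (0.75). In the tumour line 24 of 16318 genes passed the threshold, 18 higher and 6 lower. Arrays of the groups did not overlap for 1366 genes (8.37%). Beadchip 1 alone gave 29 and beadchip 2 alone 3182 genes. In a model with the beadchip as a block 251 genes passed (179 higher, 72 lower), and with the replicate number as a block 53. A limma model of only the 2 groups called 0 genes (167 at an unadjusted p under 0.05). All 24 were called with either block and moved the same way within both beadchips, for LRATD2 by 4.39 and 4.99 log2. The count was 13 without TMD231 replicate 1 and 44 without TMD231 replicate 2, and the calls were 9 higher and 8 lower without MD231 replicate 2 and 15 higher and 19 lower without MD231 replicate 3. ADGRF5, CDH11, FLG, LRATD2, SCG2 and THBS2, 6 of 16 named genes, stayed past the threshold with any 1 array left out, and ARHGAP15, ARMCX2, BST2, IRX3, KYNU, LAMA4, MERTK, MMP1, PDE9A and SERPINB2 did not for at least 1 array. Of the lists 7 passed, 6 up and 1 down. The brain metastasis list rose (median log2 0.83; adjusted p = 4.58e-13, and adjusted p = 0.000201 with an estimated correlation). Within beadchips 1 and 2 the median was 1.24 and 0.69, with the beadchip as a block 0.87, and with undetected members at their bound 0.92. Over all genes 2 of 14 members passed, and 7 adjusted over the list alone. LAMA4, a laminin chain undetected in MD231, was at least 3.61-fold (log2 3.35 ± 0.44, adjusted p = 0.00297) higher. The lung metastasis list rose (median log2 0.86; adjusted p = 1.15e-08, and adjusted p = 0.0324 with an estimated correlation). That median was 0.96 with the beadchip as a block, 1.17 and 0.45 within beadchips 1 and 2, and 0.69 with undetected members at their bound. Adjusted over the list alone 4 of 19 members passed, and over all genes 2. NF-kB targets and cytokines rose as a list (median log2 0.47; adjusted p = 6.52e-07, and adjusted p = 0.00684 with an estimated correlation, 0.104 with the block too). Undetected members at their bound gave a median of 0.43, the beadchip as a block 0.41, and beadchips 1 and 2 alone 0.25 and 0.66. Members past the threshold were 1 of 19 adjusted over the list alone and 0 over all genes. The member past it over the list alone was IL1A, interleukin 1 alpha, undetected in MD231 and at least 2.94-fold (log2 2.62 ± 0.69) higher. The interferon list, in which BST2 rose, matrix proteases and adhesion molecules (median 0.12, 0.00 at the bounds) passed upward at adjusted p = 0.00964, 0.0215 and 0.0155. NRF2 targets passed downward (median -0.19, but 0.17 under median scaling) at 0.0215. With an estimated correlation these 4 were 0.113, 0.0669, 0.168 and 0.0669, and by fry the interferon and adhesion lists had 0.181 and 0.0744. Adhesion molecules missed the threshold with the beadchip as a block (0.0705).

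The next question was which genes differed from MD231 in the same direction in ADMD231, BMD231, LMD231 and TMD231. There were 17 such genes, 11 higher and 6 lower. The named genes that rose in all 4 lines were MMP1, CDH11, EVL, an actin regulator, LRATD2, ADGRF5, AGR2, ARMCX2 and MANCR, a long noncoding RNA. Of these CDH11, EVL, LRATD2, AGR2 and MANCR were undetected in MD231, and the smallest bound over the 4 lines was 13.6-fold for CDH11, 5.04-fold for EVL, 4.32-fold for LRATD2, 4.12-fold for AGR2 and 4.15-fold for MANCR. The smallest fitted log2 change was 5.75 for MMP1, 3.48 for ADGRF5 and 3.32 for ARMCX2, which rest in part on background, as MD231 detected them on 1, 1 and 2 of 3 arrays. MERTK and the provisional loci LOC100133171 and LOC652683 also rose, and these loci are named after their values were seen. FLG, THBS2, SCG2, PDE9A, ARHGAP15 and IRX3 fell in all 4 lines. IRX3, detected on every array, fell by log2 2.21 or more in each line.

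The 4 comparisons share the MD231 arrays, so chance was simulated. In 20 runs with no change at most 0 genes were shared at the adjusted threshold, and 7 at an unadjusted p under 0.05. The data had 187 there. An MD231 array deviating over many genes was not simulated. Shared genes were 158 and 32 with the beadchip or replicate number as a block, and 18 and 1706 on beadchips 1 and 2 alone. With only the groups compared there were 0. Without MD231 replicate 3 the shared calls were 14 higher and 17 lower, and 8 higher and 7 lower without MD231 replicate 2. All 17 genes moved the same way within both beadchips in all 4 comparisons. Without MD231 replicate 2 the genes AGR2, EVL, MERTK and ARHGAP15 were no longer shared and 13 of the 17 were. MD231p, which was not used to pick these genes, lay nearer the 4 lines than MD231 for 13 of 17. CDH11, LOC100133171, LOC652683 and MMP1 were also higher in BrMD231 than in MD231p.

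**Figure D2:**
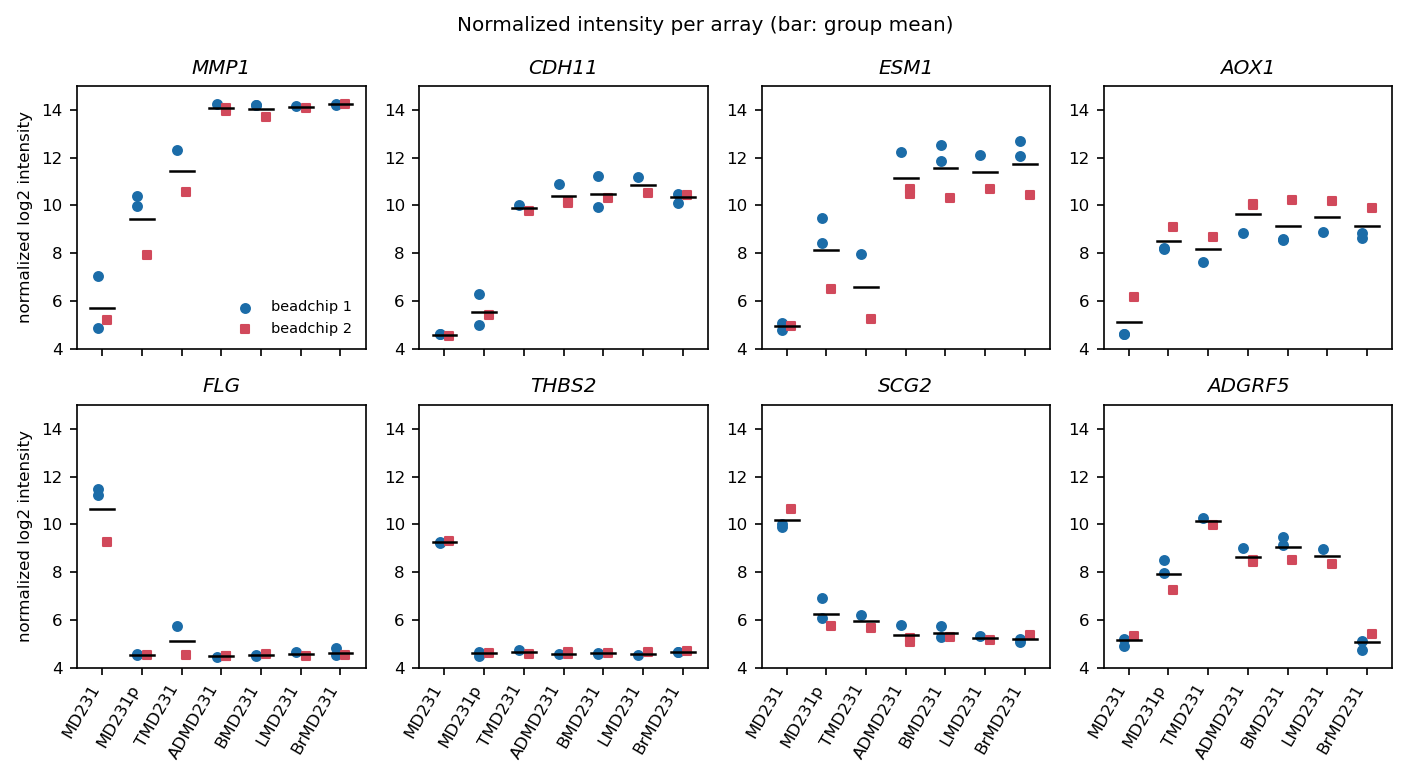
Each point is the normalized log2 intensity of 1 array for MMP1, CDH11, ESM1, AOX1, FLG, THBS2, SCG2 and ADGRF5, by group; marks tell the beadchips apart. FLG and THBS2 were detected on all 3 MD231 arrays and on no array of ADMD231, BMD231, LMD231 or MD231p.

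The brain line has its own parental culture, and the comparison asks what differs between them. In BrMD231 against MD231p (3 arrays each), MMP1 rose 28.2-fold (log2 4.82 ± 0.65, adjusted p = 0.00357) and CDH11 rose 27.7-fold (log2 4.79 ± 0.41, adjusted p = 4.30e-05). CXCL8, the neutrophil chemokine interleukin 8, listed as IL8, rose 10.5-fold (log2 3.39 ± 0.38, adjusted p = 0.000743), and SHISA2 rose 9.59-fold (log2 3.26 ± 0.42, adjusted p = 0.00259). Undetected in MD231p were TMEM47, at least 21.1-fold (log2 5.48 ± 0.81, adjusted p = 0.0086) higher in BrMD231, BST2, at least 11.1-fold (log2 4.53 ± 0.81, adjusted p = 0.0429) higher, and LRRC17, at least 8.24-fold (log2 3.92 ± 0.49, adjusted p = 0.00252) higher. KRT81, a hair keratin, fell 28.3-fold (log2 -4.82 ± 0.77, adjusted p = 0.014), LCP1, an actin-bundling plastin of blood cells, fell 9.64-fold (log2 -3.27 ± 0.42, adjusted p = 0.00259) and ADGRF5 fell 7.15-fold (log2 -2.84 ± 0.38, adjusted p = 0.00357). Undetected in BrMD231 were FERMT3, an integrin activator (kindlin 3), at least 8.38-fold (log2 -3.90 ± 0.34, adjusted p = 4.30e-05) lower, UCN2, the peptide urocortin 2, at least 5.31-fold (log2 -3.52 ± 0.38, adjusted p = 0.000589) lower, and BEX2, at least 5.23-fold lower (adjusted p = 0.0485).

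On at least 1 array of the lower group CDH11, SHISA2 and ADGRF5 were undetected, so their folds rest in part on background. Other probes of CXCL8 (0.73) and LRRC17 (0.85) gave smaller log2 changes in the same direction. In the brain line 24 of 16318 genes passed the threshold, 14 higher and 10 lower. The arrays of the groups did not overlap for 684 genes (4.19%). With the beadchip as a block 147 genes passed (107 higher, 40 lower), and with the replicate number as a block 41. Beadchip 1 alone gave 35 genes and beadchip 2 alone 2296. With only the 2 groups in the model, 2 genes passed (226 at an unadjusted p under 0.05). All 24 were called with either block and moved the same way within both beadchips, for MMP1 by 4.05 and 6.36 log2. Calls were 56 higher and 19 lower under median scaling, 15, 15 and 14 genes without BrMD231 replicate 1, BrMD231 replicate 2 and MD231p replicate 1, and 9 higher and 11 lower without MD231p replicate 3. Of 13 named genes 9 stayed past the threshold with any 1 array left out, and BEX2, BST2, KRT81 and TMEM47 did not for at least 1 array.

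In BrMD231 against MD231p 15 lists passed, 14 up and 1 down, and 8 of them with an estimated correlation. By fry 3 passed, namely brain metastasis genes, NF-kB targets and matrix proteases. The fry adjusted p was 0.243 for DNA replication, 0.132 for interferon genes, 0.0737 for adhesion molecules, 0.0882 for endothelial markers and 0.132 for cancer-testis antigens. DNA replication and G1/S genes fell as a list (median log2 -0.43; adjusted p = 0.000315, and adjusted p = 0.0425 with an estimated correlation). The median was -0.43 with undetected members at their bound, -0.43 with the beadchip as a block, and -0.39 and -0.43 within beadchips 1 and 2. Of 32 members 0 passed over all genes and 0 adjusted over the list alone. Type I interferon genes rose as a list (median log2 0.26; adjusted p = 0.000135, and adjusted p = 0.0263 with an estimated correlation). Within beadchips 1 and 2 the median was 0.24 and 0.22, with the beadchip as a block 0.26, and with undetected members at their bound 0.42. Over all genes 1 of 30 members passed, and 1 adjusted over the list alone. That member was BST2. NF-kB targets and cytokines rose as a list (median log2 0.18; adjusted p = 9.61e-05, and adjusted p = 0.0184 with an estimated correlation, 0.153 with the block too). That median was 0.18 with the beadchip as a block, 0.12 and 0.40 within beadchips 1 and 2, and 0.04 with undetected members at their bound. Adjusted over the list alone 4 of 19 members passed, and over all genes 1. CXCL1, a neutrophil chemokine undetected in MD231p, was at least 1.69-fold (log2 1.62 ± 0.45) higher. Matrix proteases rose as a list (median log2 0.34; adjusted p = 0.000348, and adjusted p = 0.0184 with an estimated correlation). Undetected members at their bound gave a median of 0.19, the beadchip as a block 0.34, and beadchips 1 and 2 alone 0.29 and 0.54. Members past the threshold were 1 of 21 adjusted over the list alone and 1 over all genes. Adhesion molecules rose as a list (median log2 0.38; adjusted p = 0.00042, and adjusted p = 0.0425 with an estimated correlation). The median was 0.42 with undetected members at their bound, 0.38 with the beadchip as a block, and 0.27 and 0.31 within beadchips 1 and 2. Of 18 members 1 passed over all genes and 2 adjusted over the list alone. CDH11 passed over all genes, and CDH10, undetected in MD231p and at least 3.16-fold (log2 2.32 ± 0.67) higher, over the list alone. Endothelial markers rose as a list (median log2 0.40; adjusted p = 5.05e-05, and adjusted p = 0.0184 with an estimated correlation). Within beadchips 1 and 2 the median was 0.39 and 0.37, with the beadchip as a block 0.40, and with undetected members at their bound 0.09. Over all genes 0 of 9 members passed, and 1 adjusted over the list alone. The member past it over the list alone was the receptor gene TIE1, undetected in MD231p and at least 6.54-fold (log2 3.52 ± 0.78) higher.

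The brain metastasis list passed upward in its own line (median log2 0.04; adjusted p = 0.000281, and adjusted p = 0.0184 with an estimated correlation, 0.103 with the block too). That median was 0.04 with the beadchip as a block, -0.01 and 0.18 within beadchips 1 and 2, and 0.04 with undetected members at their bound. Adjusted over the list alone 1 of 14 members passed, and over all genes 1. MMP1 was that member, and the mean of the list was 0.67. Within beadchip 1 the median thus had the opposite sign. Cancer-testis antigens passed upward (median log2 0.05; adjusted p = 0.00497, and adjusted p = 0.0264 with an estimated correlation, 0.0685 with the block too). Undetected members at their bound gave a median of 0.00, the beadchip as a block 0.05, and beadchips 1 and 2 alone 0.08 and -0.04. Members past the threshold were 2 of 24 adjusted over the list alone and 0 over all genes. In that list SPANXA1, undetected in MD231p, was at least 35.5-fold (log2 5.61 ± 1.24) higher and MAGEB2, undetected in BrMD231, at least 7.58-fold (log2 -4.05 ± 0.80) lower, and SPANX genes are near-identical copies whose probes were not told apart here. Within beadchip 2 the median of this list had the opposite sign. The other 7 lists lost their call with an estimated correlation, at adjusted p = 0.077 for the bone metastasis list, 0.20 for the lung metastasis list, 0.0554 for PI3K and AKT genes, 0.208 for epithelial genes, 0.208 for immediate early genes, 0.259 for ERK output and 0.259 for stem cell markers, which missed it with the beadchip as a block too (0.0856).

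The 2 parental cultures were compared because the brain line has another parent than the rest. In MD231p against MD231 (3 arrays each), UBASH3B rose 33.3-fold (log2 5.06 ± 0.96, adjusted p = 0.0326), MMP1 13.2-fold (log2 3.73 ± 0.65, adjusted p = 0.017) and ARMCX2 13.1-fold (log2 3.71 ± 0.43, adjusted p = 0.00068). LCP1 rose 11-fold (log2 3.46 ± 0.42, adjusted p = 0.000865) and AOX1 10.3-fold (log2 3.37 ± 0.62, adjusted p = 0.025). The cancer-testis genes XAGE1B and XAGE1A, near-identical copies on chromosome X, fell 58.4-fold (log2 -5.87 ± 0.58, adjusted p = 0.000127) and 57-fold (log2 -5.83 ± 0.86, adjusted p = 0.0053). BCHE, which encodes butyrylcholinesterase, fell 32.8-fold (log2 -5.04 ± 0.77, adjusted p = 0.00682), SCG2 15.4-fold (log2 -3.94 ± 0.36, adjusted p = 5.67e-05) and ARHGAP15 6.96-fold. Undetected in MD231, ABI3BP, a matrix-binding protein, was at least 28.3-fold higher, the transcription factor gene BCL11A at least 10.2-fold and EVL, an actin regulator, at least 9.2-fold. Of 2 other BCL11A probes 1 differed by log2 3.78 (mean intensity 8.04) and the other, of low mean intensity (5.14), by 0.04. FLG, THBS2 and MAP1LC3A were undetected in MD231p and at least 29.6-fold, 11.3-fold and 9.0-fold lower. The folds of UBASH3B, MMP1, ARMCX2, AOX1, XAGE1A, BCHE, SCG2 and ARHGAP15 rest in part on background, as at least 1 array of the lower group did not detect them. Smaller log2 changes in the same direction came from other probes of XAGE1B (-0.97), BCHE (-2.28) and MAP1LC3A (-1.0). In all, 62 of 16318 genes passed the threshold, 38 higher and 24 lower. Arrays of the groups did not overlap for 1058 genes (6.48%). The count was 100 on beadchip 1 alone and 3706 on beadchip 2 alone. Blocking on the beadchip, 616 genes passed (337 higher, 279 lower), and blocking on the replicate number 161. A limma model of only the 2 groups called 0 genes (462 at an unadjusted p under 0.05). All 62 were called with either block and moved the same way within both beadchips, for XAGE1B by -5.51 and -6.59 log2. Calls were 147 higher and 40 lower under median scaling, 27 and 37 genes without MD231p replicates 1 and 2, 21 higher and 27 lower without MD231 replicate 2 and 32 higher and 65 lower without MD231 replicate 3. With any 1 array left out 10 of the 16 genes named by the rule stayed past the threshold, and ABI3BP, AOX1, BCHE, BCL11A, MMP1 and UBASH3B did not for at least 1 array.

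Of the lists 4 passed between the parental cultures. Higher as a list in MD231p were brain metastasis genes (median log2 0.85; adjusted p = 1.69e-07, and adjusted p = 0.00283 with an estimated correlation). The median was 0.82 with undetected members at their bound, 0.85 with the beadchip as a block, and 0.86 and 0.41 within beadchips 1 and 2. Of 14 members 3 passed over all genes and 4 adjusted over the list alone, where FSCN1 had log2 3.11 ± 0.53 and LAMA4, undetected in MD231, was at least 2.01-fold (log2 2.51 ± 0.40) higher. NRF2 targets fell as a list (median log2 -0.35, but 0.11 under median scaling, where all genes had a median of 0.20; adjusted p = 0.00333, and adjusted p = 0.0236 with an estimated correlation). Within beadchips 1 and 2 the median was -0.39 and -0.36, with the beadchip as a block -0.35, and with undetected members at their bound -0.32. Over all genes 0 of 22 members passed, and 0 adjusted over the list alone. Cancer-testis antigens fell as a list (median log2 -0.46; adjusted p = 0.00333, and adjusted p = 0.0236 with an estimated correlation, 0.113 with the block too). That median was -0.46 with the beadchip as a block, -0.63 and -0.05 within beadchips 1 and 2, and -0.17 with undetected members at their bound. Adjusted over the list alone 2 of 24 members passed, and over all genes 1. The lung metastasis list passed upward (adjusted p = 0.00371, adjusted p = 0.415 with an estimated correlation, 0.131 by fry), with 3 of 19 over all genes tested and 5 adjusted over the list alone.

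The metastatic lines were also compared with the tumour line. In ADMD231 against TMD231 (3 arrays against 2) PGM5 was the gene past the threshold, at least 22.5-fold higher and undetected on both TMD231 arrays (log2 5.41 ± 0.71, adjusted p = 0.0311). It was 4.26 and 6.04 log2 higher within beadchips 1 and 2, and 5.31 with the beadchip as a block (adjusted p = 0.00291). The PGM5 log2 level was 10.4 ± 0.902 in ADMD231 (SD, n = 3), 9.81 ± 0.965 in BMD231 (SD, n = 3), 9.89 ± 1.25 in LMD231 (SD, n = 2) and 4.98 ± 0.155 in TMD231 (SD, n = 2). By limma 0 genes passed in BMD231 against TMD231 and 0 in LMD231 against TMD231, where 265 and 166 had an unadjusted p under 0.05. Counts with the beadchip as a block were 54, 32 and 19 for the adrenal, bone and lung lines, and with the replicate number as a block 10, 13 and 0. Beadchip 1 alone gave 0, 4 and 0, and beadchip 2 alone 3264, 2164 and 2230. Median scaling gave 24 higher and 14 lower in ADMD231, 27 genes in BMD231 and 24 in LMD231, and cyclic loess 4 higher and 7 lower, 8 and 6. Without TMD231 replicate 1 the counts were 3, 3 and 3, and without TMD231 replicate 2 they were 14, 11 and 9, all of them lower genes. The call of PGM5 was lost without any 1 of the arrays compared except ADMD231 replicate 1. It was also lost under cyclic loess, with the mean of the probes of each gene, and with only the 2 groups in the limma model (0 genes, 139 at an unadjusted p under 0.05), which gave 0 genes for BMD231 and LMD231 too (66 and 22).

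Against TMD231, lists for bone metastasis genes passed upward in each metastatic line and lost the call with an estimated correlation. By fry no list passed, and the lowest adjusted p was 0.17, 0.983 and 0.477. The bone metastasis median was 1.78 in ADMD231 (adjusted p = 0.119 with an estimated correlation), 0.48 in BMD231 (adjusted p = 0.441 with an estimated correlation) and 0.87 in LMD231 (adjusted p = 0.238 with an estimated correlation). With bounds for undetected members the medians were 1.58, 0.21 and 0.84, and 1 member passed over the list alone in each line, against 0 over all genes. MHC class II genes, which present antigen to helper T cells, passed downward in each line, with medians of -0.94 (adjusted p = 0.119 with an estimated correlation), -0.80 (adjusted p = 0.441 with an estimated correlation) and -0.88 (adjusted p = 0.135 with an estimated correlation). Within beadchip 1 those medians were -0.03, -0.05 and -0.04, and within beadchip 2 they were -1.06, -1.09 and -1.22. MHC class I genes passed downward in BMD231 (median -0.91, adjusted p = 0.441 with an estimated correlation) and LMD231 (median -0.79, adjusted p = 0.61 with an estimated correlation). For class I the beadchip 1 medians were -0.08 and -0.18, and those of beadchip 2 were -1.13 and -1.20. Of the MHC members 0 passed over all genes or over the lists alone by limma without a block. In ADMD231 matrix proteins and leukocyte markers also passed downward and YAP targets and oxidative phosphorylation upward, with 0.0801, 0.71, 0.119 and 0.71 as adjusted p with an estimated correlation, and leukocyte markers missed the threshold with the beadchip as a block (0.109). In LMD231 matrix proteins and NF-kB targets also passed downward, with 0.135 and 0.238.

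The last question was whether each of ADMD231, BMD231 and LMD231 differed from the mean of the other two. By limma 0 genes passed for ADMD231, 0 for BMD231 and 0 for LMD231, where 51, 76 and 45 had an unadjusted p under 0.05. With the beadchip as a block or the replicate number as a block the counts were again 0, 0 and 0, with 263, 284 and 229 at an unadjusted p under 0.05 under the beadchip block. Beadchip 1 alone gave 0 for each, and beadchip 2 alone gave 439, 23 and 16. Genes of cholesterol synthesis and uptake were higher as a list in LMD231 (median 0.26, 0.26 with the block, and 0.19 and 0.34 within beadchips 1 and 2; adjusted p = 0.0456, adjusted p = 0.151 with an estimated correlation). With the beadchip as a block and an estimated correlation the adjusted p = 0.00301. By fry, against no change, the adjusted p = 0.143. In ADMD231 the cholesterol list had a median of -0.27 (-0.21 with the block, and -0.23 and -0.33 within beadchips 1 and 2; adjusted p = 0.0824, adjusted p = 0.38 with an estimated correlation), and the adjusted p = 0.00131 with the block and an estimated correlation. Its median in ADMD231 without the block was 0.13 under median scaling, where that of all genes was 0.17, and -0.19 with the block. HMGCS1, an early enzyme of the pathway, was 0.71 ± 0.30 log2 in LMD231 and -1.04 ± 0.27 in ADMD231 against the other two. Of the 24 members the difference with the block was above 0 for 22 in LMD231 and below 0 for 22 in ADMD231, and 0 passed over all genes.

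Marker genes of the host organs were tested as lists. Bone and cartilage markers (6 tested) had a median of -0.11 in BMD231 against MD231 (adjusted p = 0.776), lung epithelium markers (5 tested) -0.59 in LMD231 (adjusted p = 0.339), and neuron and glia markers (11 tested) -0.08 in BrMD231 against MD231p (adjusted p = 0.958). Of the adrenal markers 4 were tested, too few for the list test, with a median of -0.28 in ADMD231.

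The change of BrMD231 from its parent was set against the mean change of the adrenal, bone and lung lines from theirs. FLG (log2 6.22 ± 0.62, adjusted p = 0.000239), THBS2 (log2 4.74 ± 0.30, adjusted p = 2.47e-06) and SCG2 (log2 3.79 ± 0.47, adjusted p = 0.00151) fell from MD231 to the 3 lines and were low in MD231p and BrMD231 alike. LRRC17 (log2 4.14 ± 0.64) was detected on all BrMD231 arrays and on no array of any other group, and CEMIP, a hyaluronan-binding protein (log2 3.84 ± 0.73), was detected on all BrMD231 arrays and on none of MD231p. TMEM98 (log2 -8.47 ± 1.10, adjusted p = 0.00243) was detected on all arrays of MD231p, ADMD231, BMD231 and LMD231 and on none of MD231 and BrMD231. ADGRF5 (log2 -6.46 ± 0.50) rose from MD231 to the 3 lines and fell from MD231p to BrMD231. PGM5 (log2 -6.09 ± 0.83), EVL (log2 -5.54 ± 0.75) and BEX2 (log2 -4.69 ± 0.70) were also lower in this difference. From MD231p to BrMD231 BEX2 fell, while PGM5 (log2 -1.05) and EVL (log2 0.14) did not pass, and EVL was already higher in MD231p than in MD231. As these genes were undetected in some groups, the differences are model values and not bounds. Other probes of LRRC17 (1.30), TMEM98 (-0.28) and PGM5 (-2.28 and -1.07) gave smaller log2 changes in the same direction. In all, 40 of 16318 genes passed the threshold, 16 higher and 24 lower. When the beadchip was a block 429 genes passed (182 higher, 247 lower), and when the replicate number was a block 102 did. Within beadchip 1 alone 39 genes passed and within beadchip 2 alone 3832. All 40 were called with either block and moved the same way within both beadchips, for ADGRF5 by -7.35 and -4.97 log2, and 9 of the 10 named genes, all but CEMIP, stayed past the threshold with any 1 array left out. The counts were 26, 26, 23, 22 and 23 without ADMD231 replicate 2, ADMD231 replicate 3, BrMD231 replicate 1, BrMD231 replicate 2 and MD231p replicate 1. With only the groups compared in the model 38 genes passed. Calls were 16 higher and 14 lower without BrMD231 replicate 3, 15 higher and 15 lower without MD231 replicate 2 and 32 higher and 27 lower without MD231 replicate 3. Brain metastasis genes were lower as a list in this difference (median -0.84, -0.91 with the block, and -0.57 and -0.61 within beadchips 1 and 2; adjusted p = 0.00206, adjusted p = 0.0342 with an estimated correlation, 0.0582 with the block too), with 0 of 14 over all genes tested and 3 adjusted over the list alone. Matrix proteins were higher (median 0.21, 0.20 with the block, and 0.21 and 0.45 within the beadchips; adjusted p = 0.00206, adjusted p = 0.0342 with an estimated correlation), with 1 of 25 over all genes tested and 1 adjusted over the list alone, namely THBS2. Over the 5 comparisons of a derived line with its parent 44 list calls were made with the preset correlation, 14 with an estimated correlation and 27 without MD231 replicate 3. Against quantile scaling, median scaling shifted the median log2 of all genes to 0.47 in ADMD231, 0.14 in BMD231, 0.27 in LMD231, 0.25 in TMD231 and 0.20 in MD231p against MD231, to 0.21 in ADMD231 against TMD231, to 0.17 and -0.14 in ADMD231 and BMD231 against the other lines, and to -0.30 in the brain difference.

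**Figure D3:**
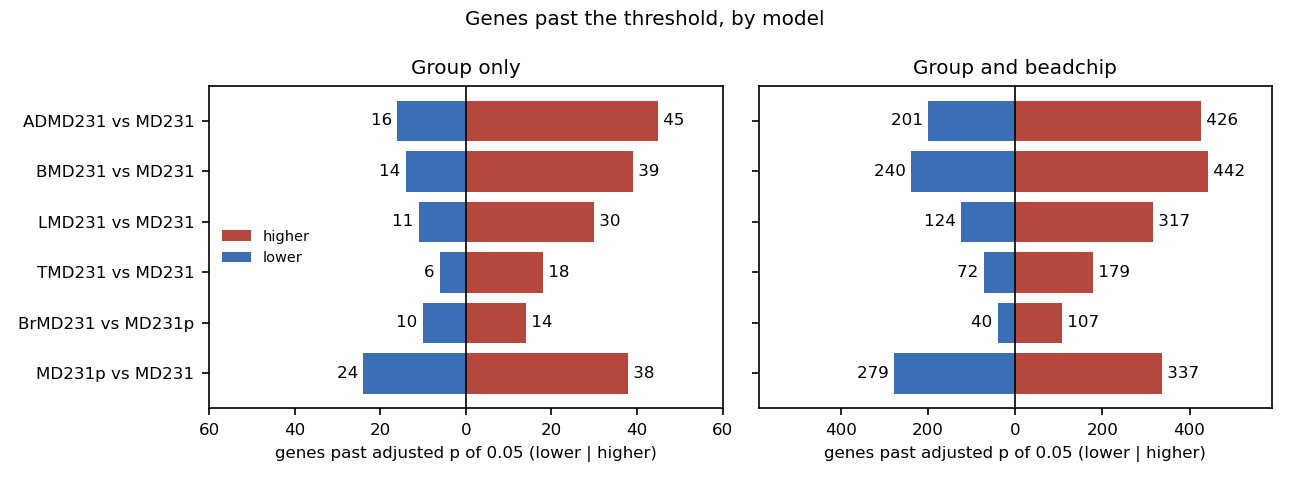
Bars give the number of genes past the adjusted threshold in 6 comparisons, higher to the right of 0 and lower to the left, with group only and with group and beadchip in the limma model. With group only 24 to 62 genes passed, and with the beadchip too 147 to 682.

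**Figure D4:**
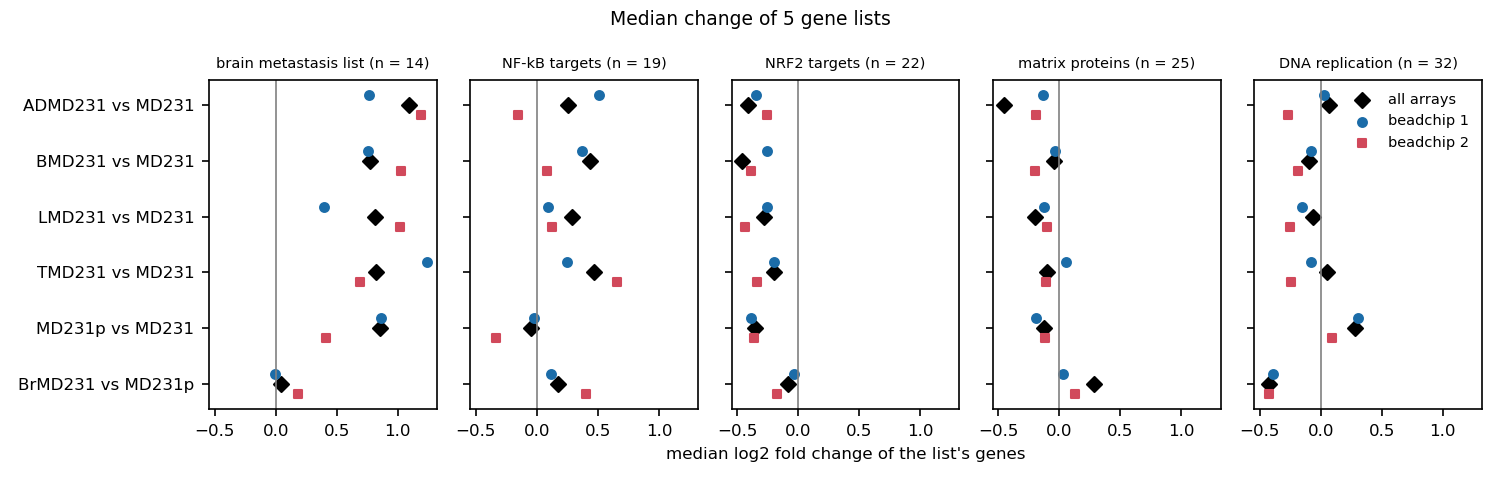
Median log2 fold changes of 5 gene lists in 6 comparisons, over all arrays and within beadchips 1 and 2. The brain metastasis list has medians of 0.77 to 1.10 over all arrays in the 4 lines set against MD231, and 0.04 in BrMD231 against MD231p.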

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

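The tests chosen only after the result was seen are those of the MD231 arrays standing apart, of the uneven spread of the groups over the beadchips, for the shared and the cholesterol genes, and of the uneven spread of the cell lines over the beadchips. The change of BrMD231 from MD231p differed from the mean change of ADMD231, BMD231 and LMD231 from MD231 for 40 genes, by a test of the difference itself. Among them were FLG (6.22), THBS2 (4.74), LRRC17 (4.14), CEMIP (3.84) and SCG2 (3.79), higher, and TMEM98 (-8.47), ADGRF5 (-6.46), PGM5 (-6.09), EVL (-5.54) and BEX2 (-4.69), lower, in log2. Brain metastasis genes were lower (-0.84) and the matrix list higher (0.21) in the same difference. Between ADMD231 and TMD231 1 gene differed, PGM5. The cholesterol list was higher in LMD231 than in the mean of ADMD231 and BMD231 (0.26; adjusted p = 0.0456), a call lost with an estimated correlation (adjusted p = 0.151). For 6 arrays in 2 groups of 3 there are 10 splits, too few for a share under 0.05, and 1 split of each 10, the real one, gave as many genes. The real and highest other counts were 61 and 0 in ADMD231 and 53 and 0 in BMD231 against MD231, 24 and 1 in BrMD231 against MD231p, and 62 and 1 in MD231p against MD231. In the last 3, where same-numbered arrays deviate together, largely by beadchip, the 3 other splits that part as many pairs gave 0.

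The 17 shared genes moved the same way within both beadchips in all 4 comparisons (100%), as their choice on these arrays favours. BMD231 and MD231 are split alike, which argues against an uneven spread of the groups over the beadchips. MD231p lay nearer the 4 lines than MD231 for 76.5%, between the bounds set for and against MD231 as the group that stands apart. In MD231p against MD231, which shares the MD231 arrays, 13 of the 17 also passed in the same direction, as either a change in the MD231 cultures or spread between these arrays would give. Without MD231 replicate 2 the change passed in all 4 comparisons for 76.5%, between the bounds for that array. AGR2, EVL, MERTK and ARHGAP15 were lost. With 17 genes and 3 MD231 arrays these explanations cannot be told apart. A change shared by the derived lines and a change in the MD231 cultures both stay open.

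The arrays of the 2 beadchips differed for 12256 of 16318 genes. Within each of the 7 lines the median absolute difference between beadchips was at least 0.96 log2, which argues against lines spread unevenly over them. Across 3829 genes the beadchip differences of 2 probes of 1 gene had a correlation of 0.298 (95% interval 0.269 to 0.326), against 0.738 (0.723 to 0.752) for differences between lines on beadchip 2. That argues against a difference in transcript levels as the whole cause, and signal lost probe by probe on beadchip 1, through RNA quality, labelling or hybridization, is a candidate explanation. Which of these steps it was stays open, as does any part due to the cultures.

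The cholesterol genes were higher in LMD231 and lower in ADMD231 than in the other metastatic lines in 4 of 4 medians within a beadchip, which argues against an uneven spread of the groups over the beadchips. With the beadchip as a block both directions stayed when any 1 of the 8 arrays was left out (8 of 8), which argues against 1 unusual array. The median of LMD231 minus ADMD231 was 0.34, between the 2 lines furthest apart, and no list of 10000 drawn at random and matched on intensity reached it (95% range -0.11 to 0.09; 0.01% with the real list counted in). That argues against a general difference in brightness at these intensities. It is no second test of the list, whose genes can vary together. A difference between the lines is a hypothesis from the same data, and culture density or medium, which the labels do not give, stays open and was not tested.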

How the results depend on the processing

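In what follows ADMD231, BMD231, LMD231, TMD231 and MD231p stand for their comparison with MD231, and BrMD231 for that with MD231p. No named gene changed the direction of its test under any setting run, and no list called in the 5 comparisons of a derived line with its parent did so under the settings run for lists. Lists called in the other comparisons were run with the estimated correlation, fry, the beadchip block and each beadchip alone. The medians of the NRF2, matrix and cholesterol lists changed sign under median scaling. Of the settings other than a left-out array 1738 values of named genes and 291 of those lists stayed past the threshold in the same direction, and 382 and 105 kept the direction and missed it; with 1 array left out these were 602 and 741, and 182 and 95. Counts stayed within 1.5 times under the authors' processed values, a detection p under 0.01, detection on every array of a group, no background correction, and normexp with an offset of 50. Fry passed 24 of the 44 lists called in these 5 comparisons. By it 3 passed in BrMD231, 0 in the 3 comparisons with TMD231 and 0 in LMD231 against the other metastatic lines. Median scaling of the arrays gave 239 in ADMD231, 161 in BMD231, 128 in LMD231, 67 in TMD231, 75 in BrMD231, 187 in MD231p, 38 in ADMD231 against TMD231, 27 in BMD231 against TMD231, 24 in LMD231 against TMD231, 1 in ADMD231 against the other metastatic lines, 107 in the brain difference and 44 in the shared change. Cyclic loess gave 11 in ADMD231 against TMD231, 8 in BMD231 against TMD231 and 6 in LMD231 against TMD231. No filter gave 2 in ADMD231 against TMD231. The mean of the probes of a gene gave 4 in ADMD231 against TMD231 and 1 in BMD231 against TMD231. Models of only the groups compared, with fewer arrays to measure the spread, gave 8 in ADMD231, 5 in BMD231, 0 in LMD231, 0 in TMD231, 2 in BrMD231, 0 in MD231p, 0 in ADMD231 against TMD231 and 0 in the shared change. The beadchip as a block gave 627 in ADMD231, 682 in BMD231, 441 in LMD231, 251 in TMD231, 147 in BrMD231, 616 in MD231p, 54 in ADMD231 against TMD231, 32 in BMD231 against TMD231, 19 in LMD231 against TMD231, 429 in the brain difference and 158 in the shared change. Beadchip 1 alone gave 106 in BMD231, 100 in MD231p, 0 in ADMD231 against TMD231 and 4 in BMD231 against TMD231. Beadchip 2 alone, whose spread rests on 1 pair of arrays, gave 5401 in ADMD231, 4249 in BMD231, 4467 in LMD231, 3182 in TMD231, 2296 in BrMD231, 3706 in MD231p, 3264 in ADMD231 against TMD231, 2164 in BMD231 against TMD231, 2230 in LMD231 against TMD231, 439 in ADMD231 against the other metastatic lines, 23 in BMD231 against the other metastatic lines, 16 in LMD231 against the other metastatic lines, 3832 in the brain difference and 1706 in the shared change. The replicate number as a block gave 165 in ADMD231, 151 in BMD231, 90 in LMD231, 53 in TMD231, 41 in BrMD231, 161 in MD231p, 10 in ADMD231 against TMD231, 13 in BMD231 against TMD231, 102 in the brain difference and 32 in the shared change. A variance trend with intensity gave 37 in ADMD231, 35 in MD231p and 2 in ADMD231 against TMD231. Array weights gave 6929 in ADMD231, 192 in BMD231, 15 in TMD231, 1684 in BrMD231, 758 in MD231p and 539 in the brain difference. An ANOVA without moderation gave 3 in ADMD231 against TMD231. The beadchip as a block with weights by beadchip, chosen after seeing the data, gave 4709 in ADMD231, 3623 in BMD231, 3803 in LMD231, 2720 in TMD231, 1936 in BrMD231, 3245 in MD231p, 2789 in ADMD231 against TMD231, 1840 in BMD231 against TMD231, 1935 in LMD231 against TMD231, 346 in ADMD231 against the other metastatic lines, 14 in BMD231 against the other metastatic lines, 10 in LMD231 against the other metastatic lines, 3229 in the brain difference and 1390 in the shared change. Of the gene lists in these 5 comparisons 14 passed with an estimated correlation, and, in tests chosen after seeing the data, 29 within beadchip 1 and 82 within beadchip 2, against 44. Except where fewer arrays entered the model, the cause was not tested.

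With each array left out in turn the counts ran from 31 (without ADMD231 replicate 2) to 1.2e+02 (without MD231 replicate 3, 44 higher and 72 lower) in ADMD231, 31 (without BMD231 replicate 1) to 84 (without MD231 replicate 3) in BMD231, 12 (without LMD231 replicate 3) to 64 (without MD231 replicate 3) in LMD231, 13 (without TMD231 replicate 1) to 44 (without TMD231 replicate 2) in TMD231, 14 (without MD231p replicate 1) to 30 (without BrMD231 replicate 3) in BrMD231, 27 (without MD231p replicate 1) to 97 (without MD231 replicate 3) in MD231p, 0 (without ADMD231 replicate 2) to 14 (without TMD231 replicate 2) in ADMD231 against TMD231, 0 (without BMD231 replicate 1) to 11 (without TMD231 replicate 2) in BMD231 against TMD231, 0 (without LMD231 replicate 1) to 9 (without TMD231 replicate 2) in LMD231 against TMD231, 22 (without BrMD231 replicate 2) to 59 (without MD231 replicate 3) in the brain difference, 14 (without MD231 replicate 1) to 31 (without MD231 replicate 3) in the shared change and 27 (without MD231 replicate 3) to 62 (without MD231 replicate 2) in the gene lists, and were 0 throughout for ADMD231, BMD231 and LMD231 against the other metastatic lines. Where LMD231 or TMD231 kept 1 array, that array is assumed to vary like the other groups. Signal over background limits what beadchip 1, with fewer probes detected, can show. A gene undetected in a group has only a bound for its fold.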

Other observations

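With the beadchip as a block, 24 genes were higher in ADMD231, BMD231, LMD231 and TMD231 than in MD231 and in BrMD231 than in MD231p. Of these 17 had a symbol other than a LOC name. The 24 include near-identical copies and so are not independent. All 24 were chosen after their values were seen, and all moved the same way within both beadchips. PTGS2, a prostaglandin synthase undetected in MD231, was at least 7.03, 10.9, 8.18 and 7.85-fold higher in the 4 lines in that order, and 2.59 ± 0.42 log2 higher in BrMD231. AFF3, a nuclear protein undetected in MD231, was at least 5.53, 7.49, 6.83 and 14.2-fold higher, and 3.47 ± 0.45 log2 higher in BrMD231. KHDRBS3, an RNA-binding protein, was 2.52 ± 0.23, 2.36 ± 0.22, 2.52 ± 0.25 and 1.84 ± 0.25 log2 higher in the 4 lines and 1.24 ± 0.22 in BrMD231. HSPA1A, a heat shock protein, was 2.07 ± 0.35, 1.97 ± 0.34, 1.97 ± 0.38 and 1.88 ± 0.38 log2 higher, and 2.83 ± 0.34 in BrMD231. LPAR1, a lysophosphatidic acid receptor, was 2.34 ± 0.23, 2.09 ± 0.23, 2.03 ± 0.25 and 3.02 ± 0.25 log2 higher, and 1.29 ± 0.23 in BrMD231. The cancer-testis genes SPANXA1, SPANXC and SPANXE, near-identical copies, were undetected in MD231p and at least 35.5-fold, 16.4-fold and 21.3-fold higher in BrMD231. Each of these 24 had an adjusted p under 0.05 in all 5 comparisons with the block, while without it PTGS2, AFF3, HSPA1A and LPAR1 passed in 0 of 5 and KHDRBS3 in 3. MD231p detected AFF3 on 1 of 3 arrays and PTGS2 and HSPA1A on 2. In the model without a block CDH11, MMP1, LOC100133171 and LOC652683 passed in all 5 comparisons.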
